A study of Homo sapiens with 2 samples.

How the data were processed

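Total RNA of 2 populations of the human lung adenocarcinoma line A549 was measured, 1 with the empty vector pEZ-Lv201 and 1 with the vector carrying FENDRR cDNA. Per the labels, the cells were G418-resistant and grown in RPMI-1640, RNA was extracted with Trizol, and it was labelled with Cy3 by a low-input amplification kit. Groups were taken from the labels, 1 array each, and the design note of the series states that there was no replicate. Per the file headers, the intensity values come from 1-colour Agilent 44K arrays scanned and read with Agilent Feature Extraction (10.7 per the labels), which subtracted the background, detrended each array multiplicatively and replaced small values by a surrogate. Per the file headers, probe positions are on hg19, and no normalization between the arrays is recorded. The deposited series matrix holds log2 values for 41093 probes, whose preparation the labels do not state. From the values themselves they are quantile-normalised, with a median of 6.15 in both columns.

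Processed signals were taken as log2, and the 75th percentile over non-control spots was subtracted from each array. Spots marked as outliers by the scanner software were left out (75 on the array labelled empty vector and 79 on the array labelled FENDRR vector), and spots of 1 probe were averaged. A probe counted as measured when the software called it well above background and unsaturated on both arrays, and the brightest such probe stood for its gene. Of 41000 non-control probes 30319 received a gene symbol, 27294 of them through the RefSeq accession in a RefSeq gene table used for names only. Of all probes 983 carry accessions of more than 1 gene, and such probes stand behind POU5F1, HSPA6 and MT1X, among others. On the array labelled empty vector 28365 probes were well above background and on the array labelled FENDRR vector 28000. A gene well above background on 1 array only was given a lower bound, with the dim signal set to at least the dimmest signal well above background.

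With 1 array per group no test was possible, so no p-value was computed, and genes were counted at 2-fold by size alone. The scanner software's error model, repeated spots and several probes of 1 gene describe the measurement, and the spread between cultures is unknown. The share of higher genes has a Wilson interval at 95%, computed as if genes were independent. Each of 44 gene lists, fixed before the files were seen, was described by the median of its measured members. The lists held 866 entries, of which 13 had no probe, and some genes were in more than 1 list. That median was set against 10000 random lists of the same size drawn from the same 20 signal bins, as a description of these 2 arrays. The genes to be named were fixed beforehand by 4 rules. These took the 15 highest and 15 lowest genes whose probes shared a direction, the 5 largest bounds each way, up to 4 members per list with the largest differences, and all measured members of the FENDRR locus and reported FENDRR target lists.

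Before the files were seen 11 alternatives were planned. They were normexp background correction with an offset of 50, median, quantile, loess and E1A spike-in scaling, no filter and a stricter filter on dim probes, the mean over probes, only genes whose probes share a direction, outlier spots kept, and the series matrix values. Another 3 were added after the data were seen. The first subtracted the median difference of the 200 surrounding spots. The second removed the trend on probe GC content and signal by lowess with a fraction of 0.4. The third subtracted the median of the 100 nearest measured genes on the same autosome. Windows of 100 consecutive measured genes, starting every 10 genes, were also added after the data were seen and set against 100 random gene orders.

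The steps were tested on simulated data with 14493 genes and a scale factor between arrays. Of simulated 1.5-fold changes 0% were counted at 2-fold, of 2-fold changes 55.1% and of 3-fold and 4-fold changes 100%. No unchanged gene was counted, and 1 of 40 null lists lay outside its range. Simulated changes were recovered with median errors of 0.033 to 0.042 in log2. The changed genes were given the noise of spots only, without the gene-to-gene variation given to unchanged genes. The percentages counted and these errors therefore follow from the simulated noise and are no detection rates for the data. In the data the scanner software's error had a median of 0.20. Differences of the 3548 dimmest genes had an SD of 0.42, real differences included. The simulation therefore does not tell how many genes in the data pass 2-fold by measurement error. Probes without a gene symbol (10681) were left out of gene counts. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.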

Results

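Gene expression was measured in A549 cells, a human lung adenocarcinoma line, in 2 G418-resistant populations. The first carried the empty lentiviral expression vector pEZ-Lv201 and the second the same vector with the cDNA of FENDRR, a long non-coding RNA whose gene lies beside the transcription factor gene FOXF1. Total RNA of each population was hybridised to 1 single-colour Agilent array, so each group held 1 sample and there were no replicates. Each array had 43376 non-control spots for 41000 probes. On the array labelled empty vector 69.2% of the probes were well above background, and on the array labelled FENDRR vector 68.3%. The 75th percentiles of signal were 702 and 692, and no spot was saturated. The number of arrays limits the precision: no test between the groups was possible, and differences are given by size only. Higher and lower below always mean on the array labelled FENDRR vector relative to the array labelled empty vector.

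The first question was whether FENDRR itself was raised. It was not seen: neither of the 2 FENDRR probes was well above background on either array. The probe at chromosome 16, 86508923 to 86508982 (hg19), had a signal of 2.26 on the array labelled empty vector and 2.39 on the array labelled FENDRR vector, and the probe at 86524544 to 86524603 had 2.15 and 2.22. Negative control spots had a median of 1.99 and 2.01, and the dimmest probe well above background had 9.01 and 9.03. On the array labelled FENDRR vector 19.2% of probes were dimmer than the brighter FENDRR probe. The labels say that FENDRR was overexpressed, and the 2 probes do not show it, so arrays are named by their label throughout. Whether the cloned cDNA contains either probe sequence is not given in the sources used here.

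Among neighbours of FENDRR on chromosome 16, the forkhead genes FOXL1 and FOXC2 were higher by 0.47 and 0.35 on the log2 scale. MTHFSD and COX4I1 differed by 0.10 and 0.05. FOXF1 and the interferon regulatory factor IRF8 were not well above background on either array. The median of the 4 measured neighbours was 0.23, inside the middle 95% of medians of random lists of the same size and signal (−0.27 to 0.24). Genes that earlier work had tied to FENDRR differed by less than 1.5-fold. Fibronectin (FN1) differed by −0.27 and the metalloproteinase inhibitor TIMP2 by −0.23. The RNA-binding protein gene ELAVL1 and the pluripotency factor POU5F1 each differed by 0.09, GATA6 by −0.07 and the gelatinase MMP9 by 0.01. MMP2, the drug efflux pump gene ABCB1, PDPN, SOX2 and NANOG were not well above background on both arrays and gave no value. The list median was −0.07, inside the random range of −0.24 to 0.22.

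**Figure D1:**
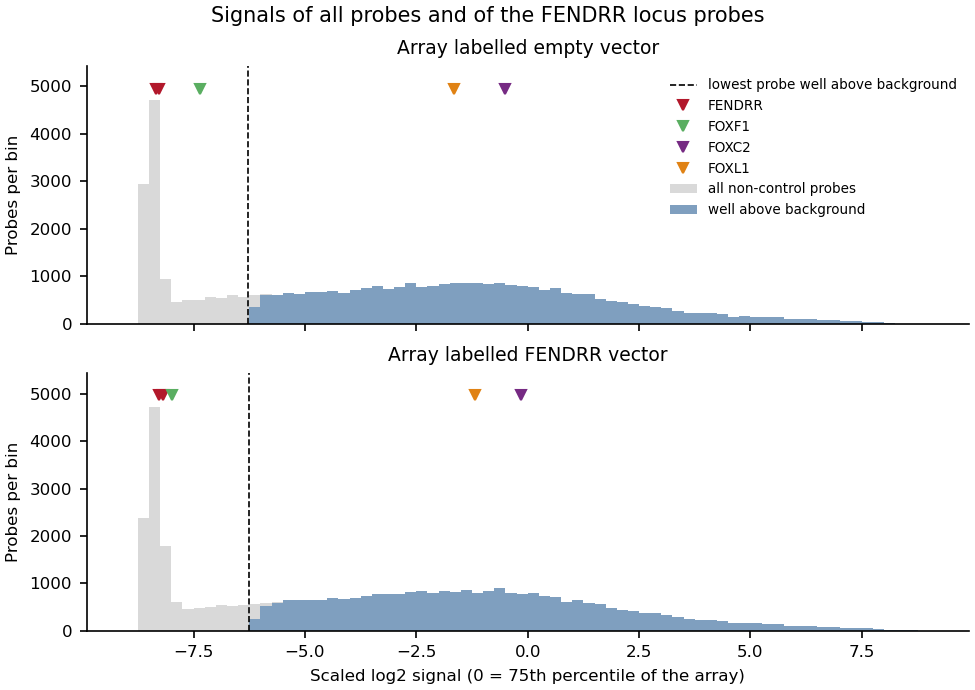
Number of non-control probes per bin of scaled log2 signal (0 is the 75th percentile of the array) on each array, with the probes well above background in blue, the dimmest of these as a dashed line and the probes of FENDRR, FOXF1, FOXL1 and FOXC2 as triangles. The FENDRR probes lie at −8.35 and −8.28 on the array labelled empty vector and at −8.28 and −8.18 on the array labelled FENDRR vector, left of the lines at −6.28 and −6.26.

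The second question was which genes differed between the 2 populations. Among genes measured on both arrays whose probes shared a direction, the largest difference was in C5AR1, the receptor for the complement fragment C5a, which was 9.37-fold higher (log2 3.23). Next came the neutrophil chemokine CXCL1 (2.11), the lipid kinase PIP5K1B (2.08), HPGD, which inactivates prostaglandins (1.99), the pentraxin PTX3 (1.95), the chemokine CXCL8 (1.91) and the cytokine receptor subunit IL20RA (1.89). The largest lower values were those of the glycosyltransferase GALNT18 (−3.06), the ileal bile acid-binding protein FABP6 (−3.02), the dehydrogenase DHRS2 (−2.65 and −2.68 by its 2 probes) and the retinaldehyde dehydrogenase ALDH1A1 (−2.47). These were followed by matrix Gla protein (MGP, −2.32), the placental insulin-like peptide INSL4 (−2.19), the collagen chain COL5A1 (−2.14), filamin C (FLNC, −2.04) and the glucose transporter SLC2A3 (−2.03). All 15 highest genes had 1 measured probe, which meets the rule of a shared direction by itself. Of the 15 lowest, only DHRS2, ZNF618, PTGS1 and NPTX1 had 2. C5AR1 rested on a signal of 14.1 on the array labelled empty vector, and GALNT18 on 9.89 on the array labelled FENDRR vector. On these arrays the dimmest signals well above background were 9.01 and 9.03.

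Of 14192 genes measured on both arrays, 47 were at least 2-fold higher and 127 at least 2-fold lower. The higher genes made up 27.0% of these (Wilson 95% interval 20.96 to 34.05, covering counting error only). With the spike-in controls as the scale, the split was 31 higher and 203 lower, or 13.2% higher, because that scale moves the median of all genes to −0.14. At 1.5-fold the counts were 314 and 565, at 3-fold 12 and 30, and at 4-fold 4 and 9. Most genes were close: 93.8% lay within 1.5-fold, and the arrays correlated with r = 0.994 across genes, which are not independent replicates. The 3548 dimmest genes held 27 of the higher and 70 of the lower genes, and the 3548 brightest 1 and 3. With another background correction (normexp), which shrinks differences of dim spots, 15 genes were 2-fold higher and 41 lower. Under it C5AR1 was at 1.46, GALNT18 at −1.04 and SLC2A3 at −1.02, while CXCL1 was at 2.03. PTX3 (0.76), IL20RA (0.68), INSL4 (−0.84) and COL5A1 (−0.72) were no longer 2-fold.

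The remaining genes with the highest values were the presynaptic gene ERC2 (1.80), the retinol carrier RBP4 (1.70), KRABD3, named KRBA1 on the array (1.69), the lysosomal enzyme GALC (1.66), the keratin KRT23 (1.58), the dynein light chain gene DYNLRB2 (1.57), the paraoxonase PON3 (1.51) and the scaffold protein HOMER2 (1.49). The remaining genes with the lowest values were ZNF618 (−1.96), SLC2A14 (−1.84), the cyclooxygenase PTGS1 (−1.83), PALM3 (−1.76), the transcription factor ARNT2 (−1.76) and the neuronal pentraxin NPTX1 (−1.73). With normexp ERC2 (0.46), DYNLRB2 (0.47), PON3 (0.90), ZNF618 (−0.42), PTGS1 (−0.32) and PALM3 (−0.71) were no longer 2-fold. SLC2A14 is a close paralog of SLC2A3, so a probe of either gene can take up the other's signal, and both values are uncertain. Repeated spots of 1 probe gave a median SD of the difference of 0.084, probes of 1 gene differed with a median SD of 0.12, and the scanner software's own error of a gene's difference had a median of 0.20. For C5AR1 that error was 0.28, for CXCL1 0.20 and for GALNT18 0.34. None of these errors includes the spread between cultures. Of the 174 genes past 2-fold, 133 had 1 measured probe. Of the other 41, 38 had all probes in the same direction, and the exceptions, named after their values were seen, were OSGEPL1 (2.17 and −0.31), PLAGL1 (−1.67 and 0.10) and PSG8 (−1.13 and 0.13).

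**Figure D2:**
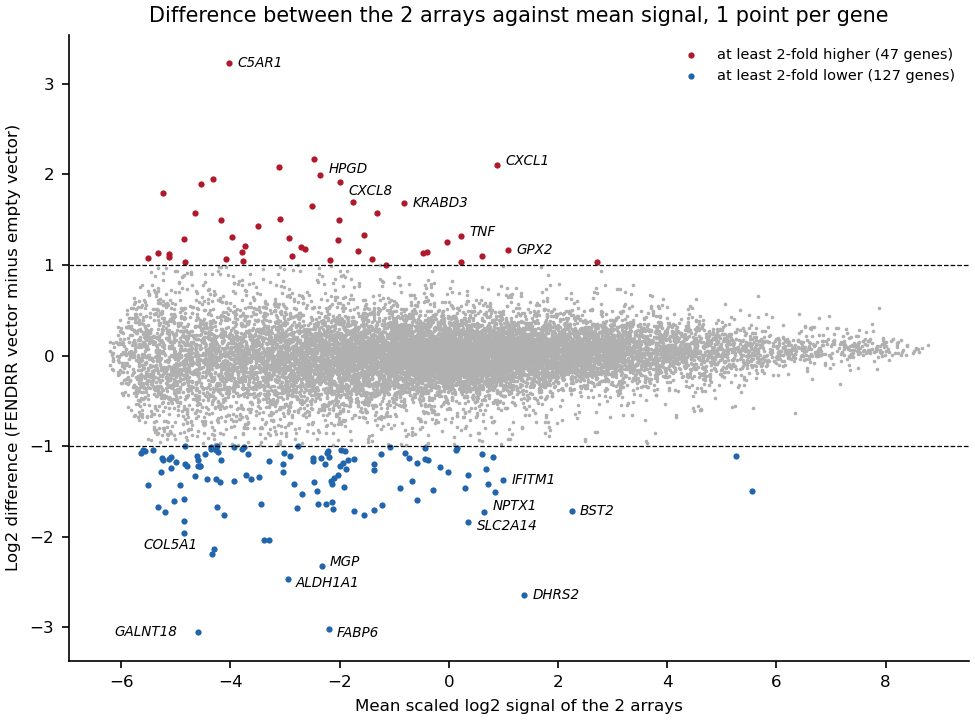
Log2 difference (array labelled FENDRR vector minus array labelled empty vector) against the mean scaled log2 signal of the 2 arrays, 1 point for each of 14192 genes, with dashed lines at 2-fold. The 47 red and 127 blue points lie mostly at low signal, and C5AR1 at 3.23 and GALNT18 at −3.06 are the extremes.

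Further genes were well above background on 1 array only, 160 on the array labelled FENDRR vector and 335 on the array labelled empty vector. For these the difference is a lower bound, the bright signal against the higher of the dim signal and the dimmest signal well above background. The long non-coding RNA LINC01094 was at least 9.58-fold higher, the GTPase-activating protein ARHGAP28 at least 4.57-fold, ZNF329 at least 4.47-fold, the neuronal nitric oxide synthase NOS1 at least 4.02-fold and the linker histone H1-1 at least 3.67-fold. In the other direction the vesicular glutamate transporter SLC17A8 was at least 22.4-fold lower, the selenium-binding protein SELENBP1 at least 17.6-fold, the BMP antagonist CHRDL1 at least 5.52-fold, the transcript KDM7A-DT at least 5.49-fold and STAC2 at least 5.33-fold. In all, 19 bounds on the higher side and 37 on the lower side reached 2-fold.

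Inflammatory genes stood out among the higher genes. Of 23 measured NF-kB targets and inflammatory cytokines, 7 were at least 2-fold higher, none was 2-fold lower, and 19 lay above 0. CXCL1 and CXCL8 led, with CXCL2 at 1.33 and tumour necrosis factor (TNF) at 1.32. The chemokine CCL20 (2.46-fold higher), interleukin-1 beta (IL1B, 1.13) and the feedback inhibitor TNFAIP3 (1.07), chosen after their values were seen, completed the 7. IL32, also chosen after its value was seen, was at −0.65. The list median was 0.34, percentile 100 among 10000 random lists matched on signal (middle 95%, −0.12 to 0.12), which describes these 2 arrays and not the conditions. Of the 7 genes past 2-fold, 4 stayed with normexp, which put CXCL2 at 0.95, CCL20 at 0.74 and TNFAIP3 at 0.86. With spike-in scaling 5 stayed, with IL1B at 0.99 and TNFAIP3 at 0.93. TNFAIP3 also fell short as the mean of its probes (0.80) and after subtraction of its neighbouring genes (0.81), and the stricter filter on dim probes kept 3.

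Targets of the oxidative stress regulator NRF2 were also higher. A549 cells are known to lack functional KEAP1, the repressor of NRF2. Of 24 measured targets 21 lay above 0 and 2 were 2-fold higher, the aldehyde dehydrogenase ALDH3A1 (1.20) and the glutathione peroxidase GPX2 (1.17). The cystine transporter SLC7A11 was at 0.79 and the export pump ABCC2 at 0.57, while the heme oxygenase HMOX1, chosen after its value was seen, was at −0.43. The list median was 0.26 (random range −0.04 to 0.12). Airway secretory and goblet markers had a median of 0.29 (−0.20 to 0.15), with 12 of 14 above 0. The secreted airway proteins BPIFB1, BPIFA1 and SCGB3A2 were at 1.14, 0.63 and 0.62, and the transcription factor FOXA1 at 0.64. With normexp ALDH3A1 was at 0.79 and BPIFB1 at 0.99, both short of 2-fold.

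Another 4 lists lay above the random range. Replication-dependent histones had a median of 0.25 (−0.10 to 0.15), with H2AC8 at 0.73, H1-4 at 0.50, H2AC4 at 0.49 and H1-2 at 0.47. Of the 15 measured, 14 lie on chromosome 6, where genes in general were higher, and after subtraction of the median of the 100 nearest genes the list median was 0.06, inside its random range of −0.10 to 0.14. The histone genes themselves counted among those nearest genes. HOX genes had a median of 0.23 (−0.17 to 0.12), with HOXC8 at 0.81, HOXA10 at 0.61, HOXA4 at −0.48 and HOXB9 at −0.80. With the stricter filter on dim probes the HOX median lay inside its random range. Coagulation and hepatic-type secreted proteins had 0.22 (−0.25 to 0.18), with ceruloplasmin (CP) at 1.04 (0.34 with normexp and 0.89 with spike-in scaling), heparin cofactor SERPIND1 at 0.90 and C5 at 0.69. The 6 measured endothelial markers had 0.30 (−0.35 to 0.26), with CLDN5 at 0.67, ERG at 0.33, PECAM1 at 0.31 and VWF at −0.35. The coagulation and endothelial lists each fell inside their ranges under 3 of 14 settings.

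**Figure D3:**
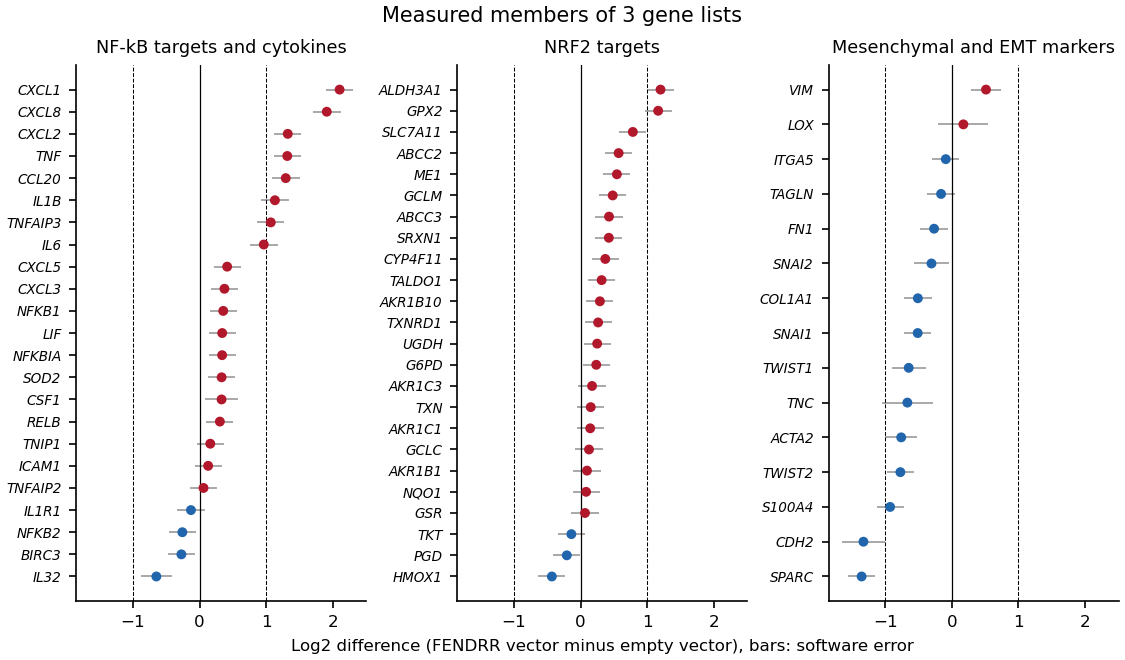
Log2 difference (array labelled FENDRR vector minus array labelled empty vector) of each measured member of 3 gene lists, with the scanner software's error of the difference as bars and dashed lines at 2-fold. In the NF-kB list 19 of 23 points lie above 0, in the NRF2 list 21 of 24, and in the mesenchymal list 2 of 15.

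Mesenchymal and extracellular matrix genes were lower. Of 15 measured mesenchymal markers 13 lay below 0, and the list median was −0.51 (random range −0.22 to 0.15). The matrix protein SPARC was at −1.36 and N-cadherin (CDH2) at −1.33, the 2 members past 2-fold. With normexp SPARC was at −0.97 and CDH2 at −0.30, so neither was 2-fold. S100A4 was at −0.93 and TWIST2 at −0.77, whereas vimentin (VIM), chosen after its value was seen, was at 0.51 on a dim probe (signal 39.8 and 56.0). Collagens and basement membrane genes had a median of −0.22 (−0.10 to 0.14), with 14 of 18 below 0. COL5A1 and COL4A6 (−1.26) were past 2-fold, and COL6A1 was at −0.59. TGF-beta targets had −0.25 (−0.14 to 0.14), with the ligand TGFB2 at −1.14 (−0.97 with normexp and −0.93 as the mean of its probes), ID2 at −0.62, TGFBI at −0.62 and COL1A1 at −0.51. The mesenchymal and TGF-beta lists share 2 genes. Epithelial markers had a median of −0.0024 (−0.06 to 0.13), with ESRP2 at 0.50, CRB3 at −0.29 and MUC1 at −0.41. The 2 probes of KRT8 went opposite ways, at −0.31 and 0.26.

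Genes of antigen presentation and of the hypoxia response were lower too. All 6 measured MHC class II genes lay below 0, with a median of −0.55 (−0.30 to 0.24). HLA-DQB1 was at −1.27 (−0.99 with normexp), HLA-DMB at −0.83 and HLA-DMA at −0.27. HLA-DPB1 was at −0.88 on a dim probe (signal 26.8 and 14.4), and between −1.02 and −0.06 over the settings. With no filter on dim probes the class II median lay inside its range. MHC class I and antigen processing genes had −0.09 (−0.09 to 0.15), just outside the range, and 5 of 15 settings placed them inside. TAP2 was at 0.53, HLA-B at −0.30 and PSMB9 at −0.26. The 2 probes of B2M went opposite ways, at −0.38 and 0.52. Hypoxia targets had −0.21 (−0.12 to 0.12), with 16 of 20 below 0. Beside SLC2A3, NDRG1 was at −0.94, EGLN3 at −0.88 and ANGPTL4 at −0.63. Metallothioneins had −0.20 (−0.04 to 0.16) with 9 of 10 below 0, among them MT1F at −0.44, MT1G at −0.27, MT1E at −0.23 and MT1X at −0.22. These genes lie together on chromosome 16, and the MT1X probe is assigned to 3 genes. Their probes may take up each other's signal, which was not checked, so the members may not be separate measurements. Oxidative phosphorylation genes had −0.02 (−0.0008 to 0.12), which turned to 0.0036 with the arrays scaled by their medians only because that scaling adds the same amount to every gene. The median lay inside its range under 2 of 15 settings. SDHB was at −0.42, SDHC at −0.31, NDUFB10 at −0.22 and NDUFB5 at −0.20.

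In all, 7 of the 44 lists lay above and 8 below their random ranges, where 2.2 would be outside if genes varied independently. Members of 1 list may vary together between any 2 cultures, and some lists share genes. The 2.2 is therefore no measure of how many lists would lie outside without an effect of the vector. The other 29 were inside, the FENDRR locus and reported target lists among them. After subtraction of the neighbouring genes some of these left their ranges. Mitosis genes (−0.0789, limit −0.0529) and ATF4 and unfolded protein response genes (−0.0588, limit −0.0555) fell below. Apoptosis regulators (0.1158, limit 0.1080), immediate early genes (0.1271, limit 0.1202) and receptor tyrosine kinases and ligands (0.1230, limit 0.1202) lay above. Interferon-stimulated genes had a median of −0.10 (−0.11 to 0.10), although the antiviral membrane proteins BST2 and IFITM1 were at −1.72 and −1.37, with OASL at 0.65 and IFI44 at 0.61. Interferons and RNA sensors had 0.07, with IRF1 at −0.21. Cell cycle genes differed little: DNA replication genes had a median of 0.05, with GINS3 at 0.34 and RFC3 at −0.33, and mitosis genes −0.04, with CENPE at −0.53 and UBE2C at 0.40. P53 targets had −0.03, with GDF15 at 0.67 and FAS at −0.51, and apoptosis regulators 0.09, with BCL2L1 at 0.44. Stemness and drug efflux genes had −0.08, with ALDH1A1 and nestin (NES, −1.53, and −0.94 with normexp) lower and ALDH3A1 higher. Receptor tyrosine kinases and ligands had 0.08, with IGF1R at −1.04 (−0.94 with normexp and −0.91 as the mean of its probes), EREG at 0.66, TGFA at 0.52 and VEGFC at 0.47. PRC2 and TrxG complex genes had −0.05, with EZH2 at 0.28 and RBBP7 at −0.56. Metalloproteinases and inhibitors had −0.06, with TIMP3 at 0.78 and MMP11 at −0.58.

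ATF4 and unfolded protein response genes had a median of −0.03, with DDIT4 at −0.94 and TRIB3 at 0.57. Heat shock genes had −0.01, with HSPA6 at −0.56, and glycolysis genes −0.03, with GPI at 0.27 and ENO1 at −0.25. Cholesterol genes had 0.05, with ACAT2 at 0.62. Fatty acid synthesis genes had −0.04, with 12 of 16 below 0, ME1 at 0.55 and ELOVL5 at −0.35. WNT targets had 0.14, with SP5 at 0.59, AXIN2 at 0.57 and RNF43 at −0.56. YAP targets had −0.01, with TGFB2, also a TGF-beta target, as the only member past 2-fold and AXL at 0.30, and immediate early genes 0.12, with DUSP6 at 0.52. Alveolar type 2 markers had −0.24, with NKX2-1 at 0.41 and LPCAT1 at −0.34, and ciliated cell markers −0.02, with CIMAP3 at −0.36 and CAPS at −0.35. Ribosomal proteins had 0.05, with RPL22 at −0.45 by its brightest probe and its 4 probes between −0.48 and 0.04, and housekeeping genes 0.02, with TBP at 0.49. Cancer-testis antigens had 0.06, with PRAME at −1.15 (−0.16 with normexp). Of the markers of cell types foreign to the culture, the endothelial list lay above its range, as given earlier, and the others inside: fibroblast markers had −0.07, with COL1A1 at −0.51, leukocyte markers 0.03, with CD3E at 0.78, and erythroid markers −0.09, with HBZ at −0.60.

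**Figure D4:**
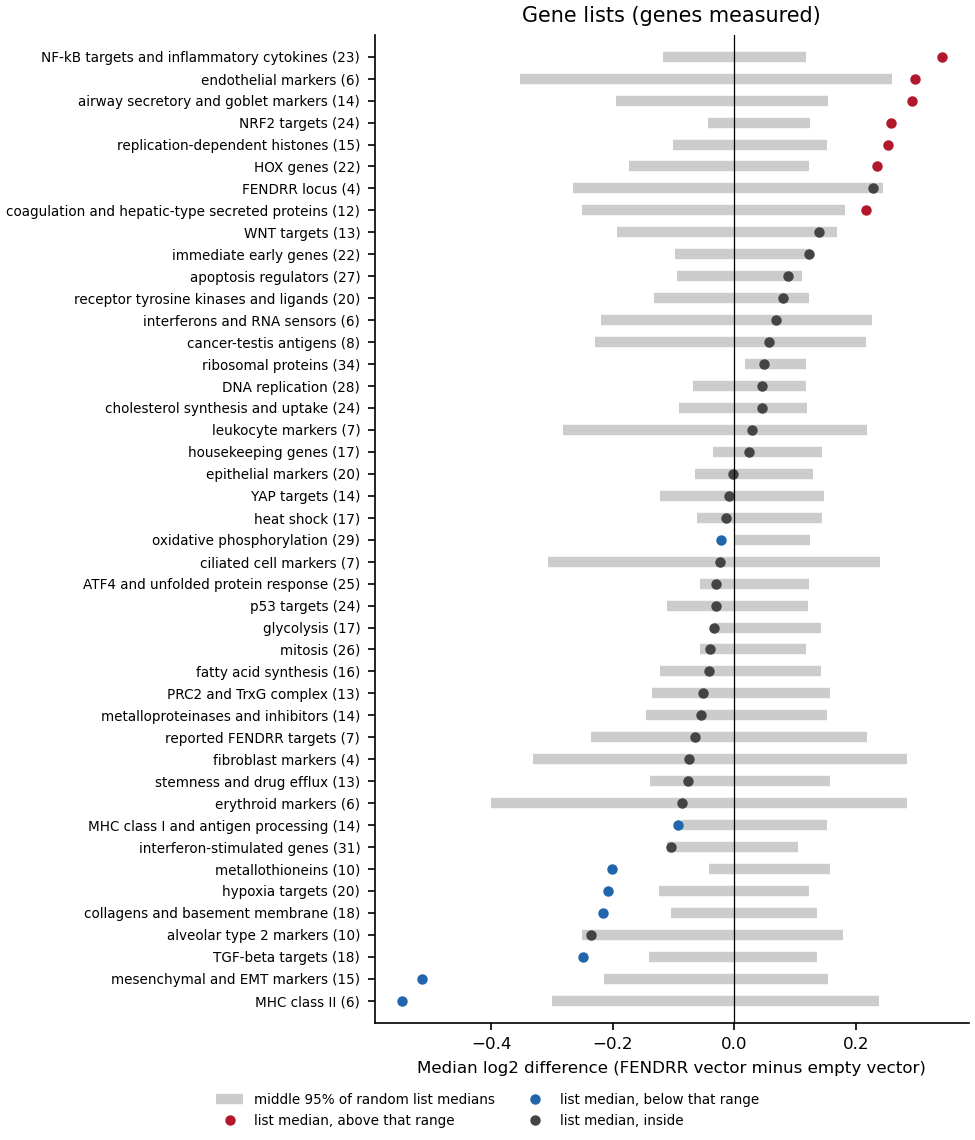
Median log2 difference (array labelled FENDRR vector minus array labelled empty vector) of each of 44 gene lists, with the number of measured genes in parentheses and the middle 95% of medians of 10000 signal-matched random lists as grey bars. The NF-kB list at 0.34 is farthest above its bar, and MHC class II at −0.55 and the mesenchymal list at −0.51 lie farthest left.

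Genes also differed together along chromosomes, an arrangement looked at only after the data were seen. In 1157 windows of 100 consecutive measured genes over 13679 autosomal genes, the lowest median was −0.25 relative to all genes. It lay on chromosome 1 from 3548815 to 16724487 (hg19), and 87 of its 100 genes were below the median of all genes. The highest was 0.30 on chromosome 6 from 132781165 to 160219153, with 83 of 100 genes above. The rest of chromosome 6 had a median of 0.13 and the rest of chromosome 1 −0.02. Windows on chromosome 20 reached 0.21, those on chromosome 5 −0.15 and those on chromosome 18 −0.14. Among chromosomes 1, 3, 6 and 20, with windows of 50 genes, the lowest median was on chromosome 3 from 186256642 to 196728689, at −0.29, ahead of chromosome 1 at −0.27, and the highest stayed on chromosome 6, at 0.31. In 100 random orders of the genes no window passed −0.13 or 0.12, and 74 observed windows did. Adjacent windows share most of their genes, so these 74 are not separate regions. In the chromosome 6 window IL20RA and TNFAIP3 were 2-fold higher and PLAGL1 2-fold lower, and in the chromosome 1 window ESPN (−1.40), PIK3CD (−1.13), HES2 (−1.12) and ARHGEF19 (−1.09) were 2-fold lower. The last 4 and PLAGL1 were chosen after their values were seen. Genes named earlier also lie in shifted regions, among them ACAT2 and TBP on chromosome 6, UBE2C on chromosome 20 and SDHB on chromosome 1. Their differences may in part be those of their neighbours.

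**Figure D5:**
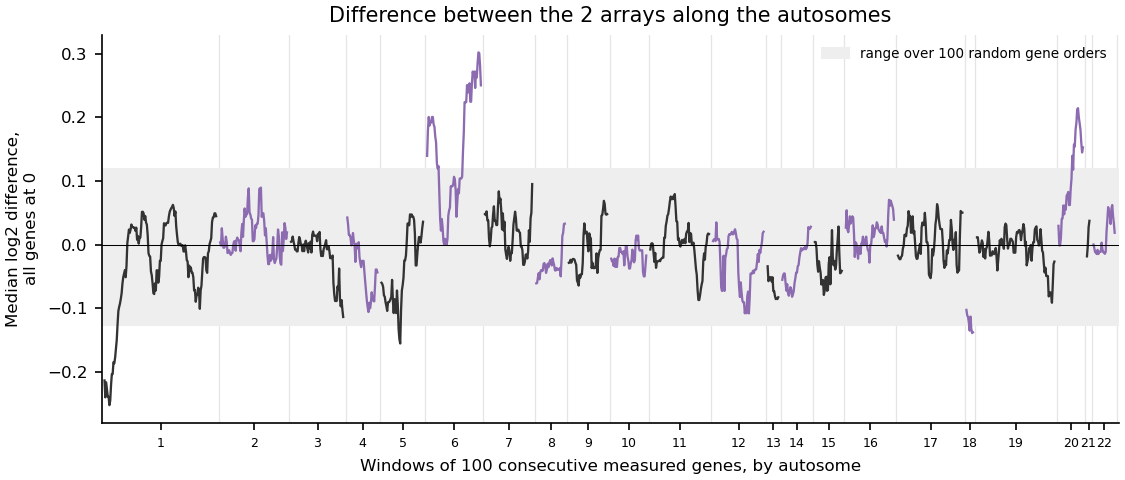
Median log2 difference (array labelled FENDRR vector minus array labelled empty vector, all genes at 0) of windows of 100 consecutive measured genes, in order along autosomes 1 to 22, with the range over 100 random gene orders in grey. The start of chromosome 1 dips to −0.25, the end of chromosome 6 reaches 0.30 and chromosome 20 reaches 0.21.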

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

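The count in this part was chosen only after the data were seen. Among 5521 measured probes without a gene symbol, which the gene counts leave out, 20 were at least 2-fold higher on the array labelled FENDRR vector and 23 at least 2-fold lower, so 46.5% of these were higher. They drew attention because they lie outside the gene counts. Of 14192 genes, 47 were higher and 127 lower at the same threshold. Relative to the numbers measured, the share of higher probes was close to that of higher genes, and the share of lower probes was smaller. The largest higher value, 1.84, belonged to a probe on chromosome 9 from 71623438 to 71623499 (hg19), beside the probe of PIP5K1B at 71623670 to 71623729, which was at 2.08. These 2 probes lie so close that they may report the same gene, which was not checked. The largest lower value, −2.27, belonged to a probe on chromosome 7 from 142500354 to 142500413. Neighbouring probes on chromosome 1 from 143256634 and from 143256725 were at −2.02 and −2.01. They are named after the same transcript and are not separate signals. No biological explanation was tested for these probes.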

How the results depend on the processing

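Of the 15 settings, 3 (spatial, probe GC and signal, and neighbouring gene correction) were chosen only after the data were seen. No paired analysis was possible because each group had 1 sample and the labels give no shared replicate numbers. Over the alternatives 2653 values of named genes stayed within the software's error and 74 moved beyond it, and 529 list medians stayed within 0.084, the spread between single repeated spots and only a rough limit for a list, 78 moved beyond it and 1 reversed. Of the 78, 44 came from E1A scaling, which lowers every gene alike and so moves all lists by construction. Both E1A and median scaling shift every gene by less than the software's error, so neither could move a named gene beyond it. Only lists outside their random ranges could count as reversed, and medians near 0 of other lists also changed sign. The median reversed was that of oxidative phosphorylation, at 0.0036 with median scaling against −0.02, because that scaling adds the same amount to every gene (the median of all genes goes from 0.0061 to 0.0314). With normexp 15 genes were 2-fold higher and 41 lower, against 47 and 127, the named genes past 2-fold numbered 25 against 46, and the rank of the brighter FENDRR probe, which is at background and measures no expression, was 17.4% against 19.2%. Normexp adds an offset, which shrinks dim differences by construction. With the stricter filter, which by construction leaves 8428 genes, there were 10 higher, 28 lower and 13 named genes past 2-fold. E1A scaling gave 31 higher and 203 lower (13.2% higher), and the cause of the offset between spike-ins and genes was not tested. Of the 15 lists outside their ranges, 8 kept their side in all 15 settings: NF-kB (0.20 to 0.39), NRF2 (0.11 to 0.29), airway secretory (0.15 to 0.43), mesenchymal (−0.66 to −0.18), TGF-beta (−0.39 to −0.21), collagens (−0.36 to −0.17), hypoxia (−0.35 to −0.16) and metallothioneins (−0.34 to −0.18). Signal over background limits the dim genes most, since 70 of the 127 lower genes were among the 3548 dimmest.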

Other observations

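The genes in this paragraph and the windows along chromosomes were chosen only after their values were seen, as were the swap, dim hybridisation, construct and proliferation tests. The nuclear long non-coding RNA MALAT1 was lower by all 5 probes, at −1.50 by the brightest (signal 55107 on the array labelled empty vector and 19225 on the array labelled FENDRR vector) and −0.36 by the least different, and NEAT1 was at −0.36. The actin-sequestering peptide gene TMSB4X was at −1.11 (39567 and 18120). The imprinted genes PEG10 and CDKN1C were at −1.64 and −1.42, and the nuclear receptor NR2F1 and its antisense RNA NR2F1-AS1 at −1.12 and −1.01. The cytokine signalling inhibitor SOCS3 was at −1.49, the adhesion molecule MCAM at −1.72 and TEX19 at −1.64. Endothelin-1 (EDN1) was at 1.25 and the EGF receptor ligand betacellulin (BTC) at 1.43.

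FENDRR was not well above background on either array, although 1 population is labelled as overexpressing it. A swap of the arrays cannot be told, since the 0 FENDRR probes well above background on the array labelled empty vector only restate the pattern. A dim hybridisation does not account for it, since spike-ins were 0.12 higher in log2 on the array labelled FENDRR vector before scaling, over 8 detected of 10 E1A probes. Whether the probes report the transcript of the construct cannot be told from a lack of overexpression, since the cloned sequence is not in the files. The rank of the brighter probe, above 19.2% of probes, carries no information on this, being at background.

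NF-kB targets and cytokines were higher on the array labelled FENDRR vector. A spatial trend does not account for it, as the list median was 0.37 after subtraction of the surrounding spots (random range −0.12 to 0.12). Nor does a trend with probe GC content or signal, as the median was 0.34 after its removal. A difference in proliferation was tested through the DNA replication and mitosis lists, whose medians of 0.0453 and −0.0406 both lay inside their ranges. After subtraction of the neighbouring genes the mitosis median was −0.0789, below its range of −0.0529 to 0.1118. The DNA replication median was then 0.0922, inside its range. A biological effect of FENDRR cannot be told from a difference between 2 cultures, because each group had 1.

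Windows of neighbouring genes on chromosomes 1 and 6 shifted together, and the predictions were written after these windows were seen but before their tests. Chance order does not account for it, as 0 of 100 random orders reached them, and neither does a trend with probe GC content or signal, as the medians were −0.24 and 0.30 after its removal. Nor do a few strongly changed genes, as only 4 and 3 of 100 genes were past 2-fold, too few to move a median, and 87% and 83% lay on the side of the window. A copy-number difference between the 2 populations stays open, because the windows had been picked by their medians, with the weaker of the dimmer and brighter genes at −0.20 on chromosome 1 and 0.27 on chromosome 6. DNA was not measured, and a regional change in transcription was not tested.

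The windows were first computed to ask why more genes were lower than higher, with a lowest window beyond −0.30 set to count for and within −0.20 to count against regional shifts. The lowest was −0.25, between these bounds. With the median of the neighbouring genes subtracted from each gene, 52 genes were 2-fold higher and 121 lower (30.1% higher), so regional shifts of that length did not account for most of the imbalance. The largest share of higher genes under the median, quantile, loess and spike-in scalings was 32.2%. The log2 difference of the 5′ probe minus that of the 3′ probe of a gene, which loss of RNA integrity would lower, had a median of −0.0069 over 4407 genes and 0.12 over the 100 of these at least 1.5-fold lower. This question was then set aside for the windows on chromosomes 1 and 6, a choice made after these values were seen.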
